A study of Mus musculus with 5 samples.

How the data were processed

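Mouse samples of 5 groups were analysed, with 1 sample in each. SOX9 ChIP-seq came from AVC and limb at embryonic day 12.5, input chromatin from whole heart at embryonic day 10.5, and RNA-seq from WT (floxed Sox9 without Cre) and Sox9 cKO (floxed Sox9 with Tie2-Cre) AVC at embryonic day 12.5. Groups were taken from the sample titles and genotype labels. Per the labels' protocols, AVCs for RNA were dissected, genotyped, checked for the level of Sox9 deletion and pooled, and 2 libraries per genotype were made. Per the labels, RNA was sequenced on Illumina MiSeq and NextSeq instruments. Whether a library was run on both is not given in the sources used here.

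The deposited expression table gives 1 FPKM value per transcript and genotype, which the authors had normalized further (nFPKM) and merged over the duplicate libraries, per the file headers. The submitters' processing notes name TopHat2, Cufflinks, edgeR and the mouse build mm9 for these samples, without versions or roles, and the further normalization step is not given in the sources used here. The table also holds the authors' log2 fold change of cKO relative to WT, a deposited comparison with no p-value beside it. The deposited peak lists hold a chromosome, start, end and a whole-number height, here treated as signal, for each peak. The submitters' processing notes name BWA and mm9 for the ChIP-seq samples. The peak caller and the meaning of the height are not given in the sources used here. The lowest height was 8 in the AVC, 28 in the limb and 20 in the input list, so the lists have different thresholds and heights were compared only within a list. There was 1 list per sample, with no replicate lists.

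The expression table held 14697 transcripts (13845 with protein-coding and 852 with non-coding RefSeq identifiers), named by the symbols in the table. The nFPKM summed to 961487 in WT and 960481 in cKO, and none was 0. FPKM steps depend on transcript length and each value merges libraries, so counts could not be recovered; depth is unknown, and no intervals were given for expression. The log2 ratio of cKO to WT was computed with a pseudocount of 1, which understates the ratio of low genes, for transcripts with at least 1 nFPKM in either genotype. This removed 904 transcripts and kept 13793. With 1 value per genotype no test was possible, and a rule of size was applied, an absolute log2 ratio of at least 1. The authors' log2 fold change was higher than the log2 ratio of the deposited values by 0.11 (0.10 to 0.11 among 1469 transcripts with at least 100 nFPKM in both), and its own median was near 0, at -0.0043. Across transcripts its correlation with the ratio used here was 0.995. Named ratios were therefore given relative to the all-transcript median of -0.11.

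The 17 gene lists (valve transcription factors, cartilage genes, valve matrix, BMP and TGF-beta, Notch and Wnt signalling, cell cycle, markers of endothelium, cardiomyocytes, valve mesenchyme, epicardium, erythroid cells, macrophages and neural crest, glia and neurons, immediate early genes, hypoxia and glycolysis, and sex-linked genes), the named-gene rule, the tests and the alternatives were fixed before the data were examined. Further lists and alternatives chosen later are named as such. Each list median was ranked among 10000 random lists of equal size drawn within 20 bins of expression, and a list was called shifted below percentile 2.5 or above 97.5. The number of members above the all-gene median was ranked in the same way, and is given where it goes against the call from the median. Named genes were Sox9, the 12 protein-coding genes with the largest ratio in each direction among those with at least 3 nFPKM in either genotype (predicted genes left out), up to 4 members of each list with the largest absolute ratio, and valve transcription factors with an absolute log2 ratio of at least 0.5, before centring. A few genes that the rule names are not reported here.

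In the limb list, 636 of 9725 lines repeated an earlier line and were counted once. Peaks were called overlapping with at least 1 bp in common, and shares have Wilson 95% intervals, which cover counting error only. Chance overlap was taken from 10000 circular shifts of the peaks within the span of peaks on each chromosome, two-sided. Shifts keep the spacing of peaks, but they also place peaks in sequence where no read maps uniquely, which lowers chance overlap. Starts were converted to count from 1. The input came from an earlier stage and from whole heart, so it is not a matched control for either tissue, and its regions are much wider than the peaks.

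Positions of genes relative to peaks, peaks near genes with expression differences and SOX motifs in peaks were planned only with annotation or sequence of mm9. These were not used here, and these steps were not run. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data. For the cKO and WT comparison with 13675 simulated transcripts, the 2-fold rule recovered 100 of 100 transcripts set to a log2 change of 3 and 100 of 100 set to 1.5, and called 0 of 13475 unchanged ones. The simulated noise had the same size at every expression level, and changes were set only in transcripts with at least 5 nFPKM in WT. The real ratios spread more at low levels, so these counts check the computation and give no error rate for the rule. Of 102 random lists without a shift, 5 fell outside the middle 95%, and 102 of 102 lists shifted by 0.5 were called. In 20 simulated AVC lists with no planted overlap with the limb, 1 had a p under 0.05, and 67 and 804 planted overlaps were counted as 71 and 811. The alternatives tried were other pseudocounts, filters, centring, a lower fold threshold, the authors' fold change, other definitions of overlap and stricter peak lists.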

Results

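SOX9 is a transcription factor required in cartilage and in the developing heart valves. Its binding sites were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the atrioventricular canal (AVC) and the limb of mouse embryos at embryonic day 12.5. The AVC is the region between the atria and the ventricles in which the endocardial cushions, the precursors of the valves, form. Unprecipitated chromatin (input) from whole hearts at embryonic day 10.5 served as background. Gene expression was measured by RNA-seq in AVCs at embryonic day 12.5 from control embryos, labelled wild-type (WT), and from embryos in which Sox9 was deleted with Tie2-Cre (cKO). Per the labels, the controls also carried floxed Sox9 alleles but no Cre, so the groups differ in the presence of Cre as well. Tie2-Cre recombines in endothelial cells and their descendants, which include much of the cushion mesenchyme, and in blood lineages. The dissected AVC also holds myocardium. Each of the 5 groups had 1 sample. For RNA, the labels state 2 libraries per genotype from pooled AVCs, and the deposited table gives 1 merged value per genotype. The spread between replicates is therefore unknown, and the genotypes are compared by size of difference alone, with no p-value. The read depth behind the expression values is unknown.

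Sox9, the targeted gene, was lower in the cKO value. Its transcript (NM_011448) stood at 36.7 nFPKM, the authors' normalized FPKM (fragments per kilobase of transcript scaled to the mapped total), in WT and at 14.7 nFPKM in cKO. The log2 ratio of cKO to WT was -1.27 with a pseudocount of 1, and -1.19 in the authors' deposited table. The remaining Sox9 signal is not divided between cell types in these values. Which exons the transcript value covers is not given in the sources used here.

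The question of the RNA comparison was which AVC genes differ in expression without Sox9. Some genes of cartilage-type matrix, several transcription factors of the valve mesenchyme and some other matrix genes were lower in cKO. Erythroid, hypoxia-responsive and epicardial genes were mostly higher. Of 13793 transcripts with at least 1 nFPKM in either genotype, 82 were at least 2-fold higher and 135 at least 2-fold lower in cKO. The median log2 ratio of these transcripts was -0.11. All log2 ratios from here on are given relative to that median ("relative log2 ratio"), while counts of genes that met the 2-fold rule are without this centring unless stated. With the centring, 115 transcripts were at least 2-fold higher and 93 at least 2-fold lower, so that the share of higher ones among them went from 37.8% to 55.3%. The middle 90% of relative log2 ratios ran from -0.45 to 0.49 over all transcripts. It ran from -0.66 to 0.70 where the higher of both values was between 1 and 3 nFPKM, and from -0.33 to 0.38 between 30 and 100 nFPKM.

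**Figure D1:**
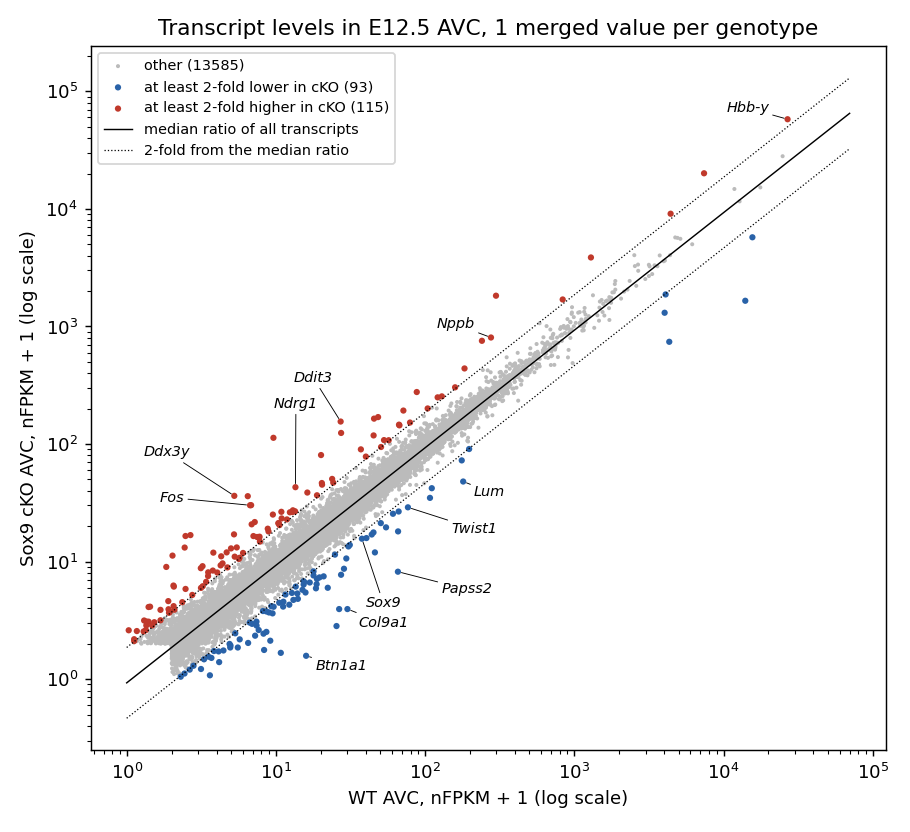
Transcript levels in E12.5 AVC, with WT nFPKM + 1 on the x axis and Sox9 cKO nFPKM + 1 on the y axis (both log scales), 1 point per transcript and 1 merged value per genotype. The solid line is the median ratio of all transcripts, the dotted lines are 2-fold away from it, and the 115 red and 93 blue points lie beyond them, with Col9a1, Papss2, Twist1 and Sox9 among the lower and Ddit3, Ndrg1 and Ddx3y among the higher.

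Among protein-coding genes with at least 3 nFPKM in either genotype, the largest differences towards lower values in cKO included several genes of extracellular matrix. Papss2, an enzyme that makes the sulfate donor for proteoglycans, stood at 64.7 nFPKM in WT and 7.20 in cKO, a relative log2 ratio of -2.90. Col9a1 (29.2 and 2.94 nFPKM) and Col9a3 (25.5 and 2.94 nFPKM), which encode chains of type IX collagen, had relative log2 ratios of -2.83 and -2.64. The matrix genes Matn4, Prelp and Lum had relative log2 ratios of -2.58, -2.13 and -1.80. The lowest 12 also held Btn1a1 (-3.23), Mstn, which encodes myostatin (-3.07), Dct of melanin synthesis (-2.01), Guca2b (-1.84) and Shisa2 (-1.76). In the other direction, 4 of the highest 12 were the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d. The others were Prl8a2 (2.84), Ddit3, a transcription factor of the stress response (2.62), Derl3 of endoplasmic reticulum protein degradation (2.58), Uts2d (2.39), Bhlhe40 (2.29), Fos (2.27), Ppm1h (2.25) and Egr1 (2.11). Ddit3 stood at 26.2 nFPKM in WT and 154 in cKO. Matn4, Prelp, Dct, Btn1a1, Mstn, Prl8a2, Derl3, Uts2d, Uty and Kdm5d were under 2 nFPKM in 1 genotype, where the pseudocount understates the ratio.

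Gene groups were described with 17 lists fixed before the data were examined. The median of each list was ranked among the medians of 10000 random lists of the same size matched on expression. This rank describes these values and carries no replicate error. Of the 17 list medians, 13 lay outside the middle 95% of their random lists, against 0.85 expected for independent lists with no shift. Genes of 1 list are often co-expressed, so a rank is not a p-value.

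Transcription factors of valve development were mostly lower in cKO. All 36 listed genes passed the filter, 27 of them were below the all-gene median, and their median relative log2 ratio of -0.26 was below that of all 10000 random lists. The list was drawn up with the theme of the study known, so it is not independent evidence of direction. The 2-fold rule was met by 7 of them, all lower in cKO, Sox9 included. Scx, a factor of tendon and valve progenitors, stood at 11.3 nFPKM in WT and 3.29 in cKO, a relative log2 ratio of -1.41. Twist1, a factor of cushion mesenchyme, stood at 75.7 and 27.9 nFPKM (-1.30). The homeobox genes Meox1 (-1.14), Prrx1 (-0.99) and Msx1 (-0.95) also met it, and the last 2 of these no longer did after centring. Below the 2-fold rule, relative log2 ratios were -0.87 for Mecom, -0.86 for Osr1, -0.73 for Snai1, -0.70 for Sox4, -0.56 for Tbx3, -0.54 for Hand2, -0.53 for Snai2 and -0.49 for Tbx2. No listed factor met the rule in the higher direction. Gata4 (231 and 207 nFPKM, -0.05) and Nfatc1 (46.2 and 46.7 nFPKM, 0.12), singled out after their values were seen, stood near the all-gene median. In the same values, the medians of erythroid, epicardial and endothelial marker lists stood above the all-gene median, at 1.10, 0.53 and 0.29. The values are not divided between mesenchyme, myocardium and other cells. A lower level of these factors in the same cells and a different cell makeup of the pools can therefore not be told apart here.

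Cartilage genes divided into a set that was several-fold lower in cKO and a set near the all-gene median. Of 15 listed genes that passed the filter, 5 met the 2-fold rule, all lower in cKO, namely Col9a1, Col9a3, Matn4, Col9a2 (13.0 and 3.82 nFPKM, -1.44) and Sox5, a partner of SOX9 in cartilage (10.2 and 3.55 nFPKM, -1.20). Col2a1, which encodes type II collagen, stood at 63.2 nFPKM in WT and 54.9 in cKO (-0.09), and Hapln1, a hyaluronan link protein, at 149 and 145 nFPKM (0.07); Sox5, Col2a1 and Hapln1 are named after their values were seen. The list median was -0.25, percentile 0.33 of its random lists, and the mean was -0.75. The number of genes above the all-gene median, 4, was at percentile 4.38, inside the middle 95%. Without the filter on low values the percentile was 4.47, inside the middle 95%.

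Valve matrix genes showed a small shift towards lower values with a few larger differences. The median relative log2 ratio of the 43 listed genes was -0.12, below that of all 10000 random lists, and 28 of them were below the all-gene median. The 2-fold rule was met by Lum (lumican, 179 and 47.0 nFPKM, -1.80), Mfap4 (110 and 41.1 nFPKM, -1.29) and Eln (elastin, 59.9 and 24.5 nFPKM, -1.15). Postn (periostin), the most abundant listed gene in WT, stood at 973 nFPKM in WT and 487 in cKO (-0.89). Markers of valve mesenchyme had a median of -0.50 over 16 genes, below all random lists, and 13 were below the all-gene median. Papss2, Twist1 and Prrx1 met the 2-fold rule. Of these 16 genes, 7 are also in another list. Without them the median was -0.07, at percentile 9.38 of its random lists, so the call of this list depends on the shared members. That alternative was chosen after seeing the data. Some members held by no other list were also lower, with Papss2 at -2.90, Ptn at -0.67 and Pdgfra at -0.61. Others, Dlk1 (0.41), Vim (0.19) and Cdh2 (0.05), stood above the all-gene median. All of these but Papss2 are named after their values were seen.

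**Figure D2:**
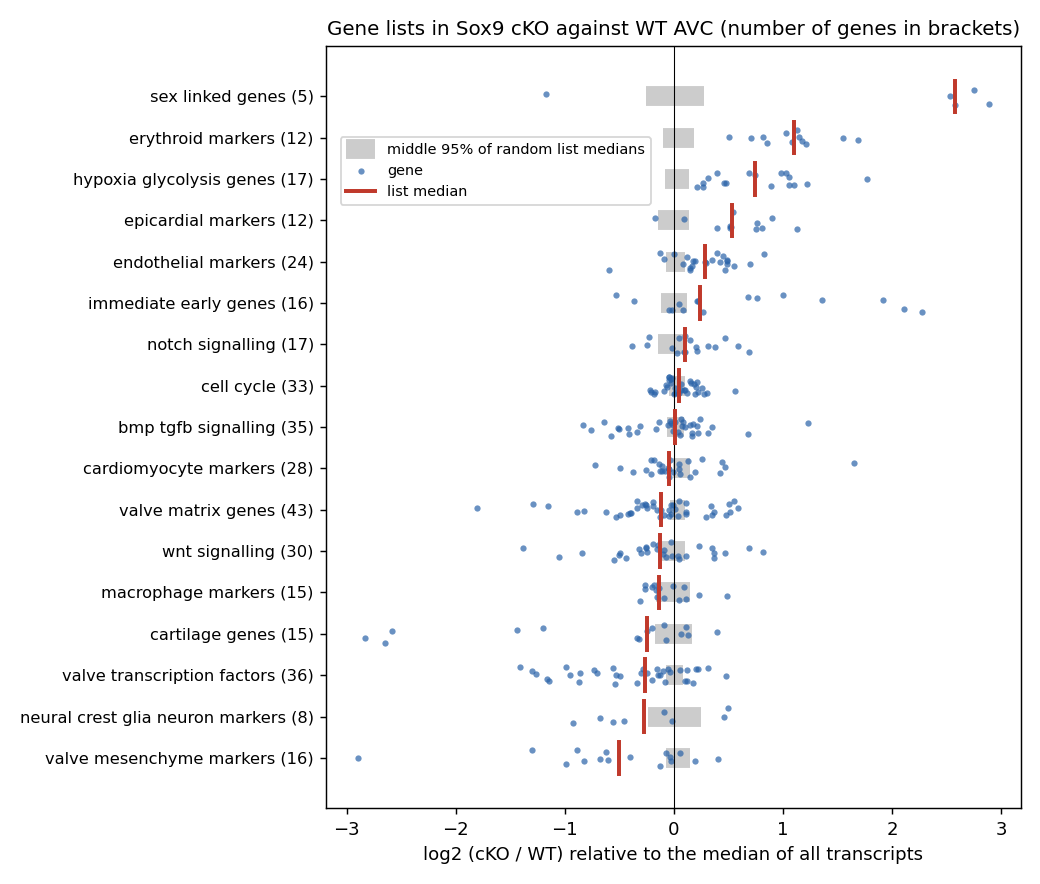
Relative log2 ratio of Sox9 cKO to WT AVC (x axis, log2 units, 0 is the median of all transcripts) for the members of 17 gene lists, with the number of genes in brackets. Blue points are genes, red bars list medians and grey bars the middle 95% of medians of 10000 expression-matched random lists; the median of valve transcription factors lies at -0.26 and that of erythroid markers at 1.10.

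Among 3 lists of signalling genes, the median of Wnt genes was shifted towards lower values, and the medians of BMP and TGF-beta and of Notch genes lay inside the middle 95% of their random lists. The median of 35 genes of BMP and TGF-beta signalling was 0.01 (percentile 53.0). Among them, Bmp10, a ligand made by trabecular myocardium, met the 2-fold rule (65.8 and 145 nFPKM, 1.23), while Ltbp3, Id4 and Bmp2 had relative log2 ratios of -0.84, -0.76 and -0.64. Id1, Id2, Id3 and Tgfbr3, named after their values were seen, stood at -0.51, -0.58, -0.50 and 0.68. Of the 35 genes, 18 were above the all-gene median, so the list median does not describe each part of the pathway. Of 17 Notch pathway genes none met the rule and the median was 0.10 (percentile 96.0), but 13 were above the all-gene median, a number at percentile 99.3 of the random lists and outside their middle 95%. Lfng (0.69), Hey2 (0.59) and Dll4 (0.47) stood highest among them and Dll1 lowest (-0.39). The median of 30 Wnt pathway genes was -0.12 (percentile 1.24), while the number above the all-gene median, 10, was at percentile 4.70, inside the middle 95%. The secreted Wnt inhibitors Sfrp2 (53.7 and 18.5 nFPKM, -1.38) and Notum (8.31 and 3.17 nFPKM, -1.05) met the rule in the lower direction, and Frzb stood at -0.84. Dkk1, another secreted Wnt inhibitor, stood at 0.25 and 1.04 nFPKM (0.81). Without the filter on low values the Wnt percentile was 2.71, inside the middle 95%. None of 33 cell cycle genes met the rule, and their median was 0.05 (percentile 68.3). Cdkn1a, an inhibitor of cyclin-dependent kinases, stood at 0.56, and Ccne1, Pcna and Cdc20 at -0.22, -0.21 and -0.18. Named list members were picked by the ratio before centring, which favours genes on the lower side. Of the 33 genes, 20 were above the all-gene median and 13 below. Cdkn1c (0.30), Mki67 (0.28) and Ccnd2 (0.26), named after their values were seen, stood further from that median than Ccne1.

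Markers of other cell types moved by different amounts. All 12 erythroid genes that passed the filter were above the all-gene median, with a median of 1.10, and 6 of them met the 2-fold rule. The embryonic globins Hbb-y (26865 and 57953 nFPKM, 1.21), Hba-x (7403 and 20102 nFPKM, 1.55) and Hbb-bh1 (1291 and 3863 nFPKM, 1.69) had the largest ratios. The 5 globin genes in the table made up 4.24% of the summed nFPKM in WT and 9.65% in cKO; reads can be shared between near-identical globin copies, so single globin values are uncertain. The median of 12 epicardial markers was 0.53, with Krt19 (1.13), Lrrn4 (0.90), Upk1b (0.80) and Wt1 (0.76) the highest. The median of 24 endothelial markers was 0.29, with 20 above the all-gene median and none past the 2-fold rule. Emcn (77.1 and 128 nFPKM, 0.82), Plvap (0.70) and Icam2 (0.55) stood highest and Cldn5 lowest (-0.59). The medians of these 3 lists were above those of all 10000 random lists. The 28 cardiomyocyte markers had a median of -0.04 (percentile 0.25) and a mean of 0.02, which differ in sign. Nppb, a natriuretic peptide gene, met the rule (275 and 805 nFPKM, 1.65), while Sln, Myh6 and Hcn4 had relative log2 ratios of -0.72, -0.49 and -0.37. Ttn, Nppa and Actc1, named after their values were seen, stood at 0.47, 0.44 and 0.43. Of the 28 markers, 11 were above the all-gene median and 17 below. The 15 macrophage markers had a median of -0.14 (percentile 4.43), with Ptprc at -0.31, Lyz2 at -0.27, Tyrobp at -0.26 and Cd68 at 0.48. The 8 neural crest, glial and neuronal markers had a median of -0.27 (percentile 1.34), while the number above the all-gene median, 2, was at percentile 9.54, inside the middle 95%. Among them Sox10 (1.73 and 0.34 nFPKM, -0.93) met the rule before but not after centring, and Erbb3, Tubb3 and Fabp7 stood at -0.68, -0.56 and -0.46. Ednrb (112 and 147 nFPKM, 0.50) and Stmn2 (0.46), named after their values were seen, went the other way. With a pseudocount of 5 the percentile of this list was 7.14, inside the middle 95%.

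Genes of the hypoxia response and several immediate early genes, which respond to stimulation within minutes, were higher in cKO in the same values. All 17 listed genes of the hypoxia response and glycolysis were above the all-gene median, and their median of 0.74 was above that of all 10000 random lists. Ndrg1 (12.5 and 41.9 nFPKM, 1.77) and Ankrd37 (6.48 and 15.2 nFPKM, 1.22) met the 2-fold rule, and 6 genes met it after centring, Adm (1.10) and Egln3 (1.06) among them. The median of 16 immediate early genes was 0.24, also above all random lists, and 4 met the rule in the higher direction. These were Fos (5.71 and 29.1 nFPKM), Egr1 (19.1 and 79.6 nFPKM), Ier3 (47.4 and 168 nFPKM, 1.91) and Nr4a1 (15.2 and 37.7 nFPKM, 1.36), while Jun, named after its value was seen, stood at -0.53. For both lists, an effect of the deletion cannot be told apart from a difference in the handling of the pools. The pools also differed in sex-linked genes. The Y-linked Ddx3y (4.26 and 35.2 nFPKM, 2.89), Uty (1.67 and 15.8, 2.76), Eif2s3y (5.48 and 35.0, 2.58) and Kdm5d (1.45 and 12.2, 2.53) were higher in cKO. The median of the 5 sex-linked genes, 2.58, was above all random lists, while the number above the all-gene median, 4, was at percentile 89.4, inside the middle 95%. Xist, which is transcribed from the inactive X chromosome of females, stood at 175 nFPKM in WT and 71.6 in cKO (-1.17).

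The question of the ChIP-seq comparison was where SOX9 binds in the AVC and how far these sites are shared with the limb. About 29% of AVC peaks coincided with a limb peak, far above the share after random shifts, and the share was highest among the tallest peaks. The authors' list held 2603 AVC peaks with a median width of 292 bp, and the limb list held 9089 distinct peaks with a median width of 297 bp. Heights are the authors' own values and are used within a list. They ran from 8 to 188 in the AVC, where 43.7% of peaks stood at the minimum, and from 28 to 292 in the limb. The input list held 14219 regions with a median width of 6703 bp, 118 Mb in all. Of the AVC peaks, 222 (8.53%, Wilson 95% interval 7.52 to 9.66) overlapped an input region, 1.72 times the 4.97% found on average after random shifts along each chromosome. Of the limb peaks, 750 (8.25%, interval 7.70 to 8.84) did so, 1.64 times the 5.04% after shifts. Both had p = 1e-04 (two-sided permutation test by 10000 circular shifts), the smallest p these shifts can give. Peaks over input regions were then removed.

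Of the remaining 2381 AVC peaks, 699 overlapped 1 or more of the 8339 remaining limb peaks. This is 29.4% (Wilson 95% interval 27.6 to 31.2, counting error only). Random shifts gave a mean of 5.00 peaks, or 0.21%, and at most 14 (p = 1e-04, two-sided permutation test, the smallest the 10000 shifts can give). Seen from the limb, 700 of 8339 peaks (8.39%, interval 7.82 to 9.01) overlapped an AVC peak. The midpoints of paired peaks lay a median of 35 bp apart. In the AVC, the shared share went from 11.8% (interval 10.0 to 13.9, 1066 peaks) at height 8 through 34.8% (30.1 to 39.9, 356 peaks) at heights 10 to 11 to 97.4% (91.1 to 99.3, 76 of 78 peaks) at heights 31 to 188. In the limb it went from 3.01% (2.49 to 3.64, 3421 peaks) at heights 28 to 35 to 72.7% (61.9 to 81.4, 77 peaks) above height 150. Heights in the 699 pairs had a Spearman rho of 0.56 across peaks (permutation p = 1e-05, the smallest 100000 permutations can give); peaks are not independent replicates. The share moved to 19.2% with the limb list limited to its tallest peaks, as many as in the AVC list. There was 1 library per tissue, so the overlap compares these libraries. Random shifts place peaks anywhere along a chromosome, so a tendency of both lists towards open or gene-rich chromatin is not in this chance level. The input is not a matched control. Whether shared peaks, the tall ones included, are SOX9 binding or sites called without it was therefore not tested.

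**Figure D3:**
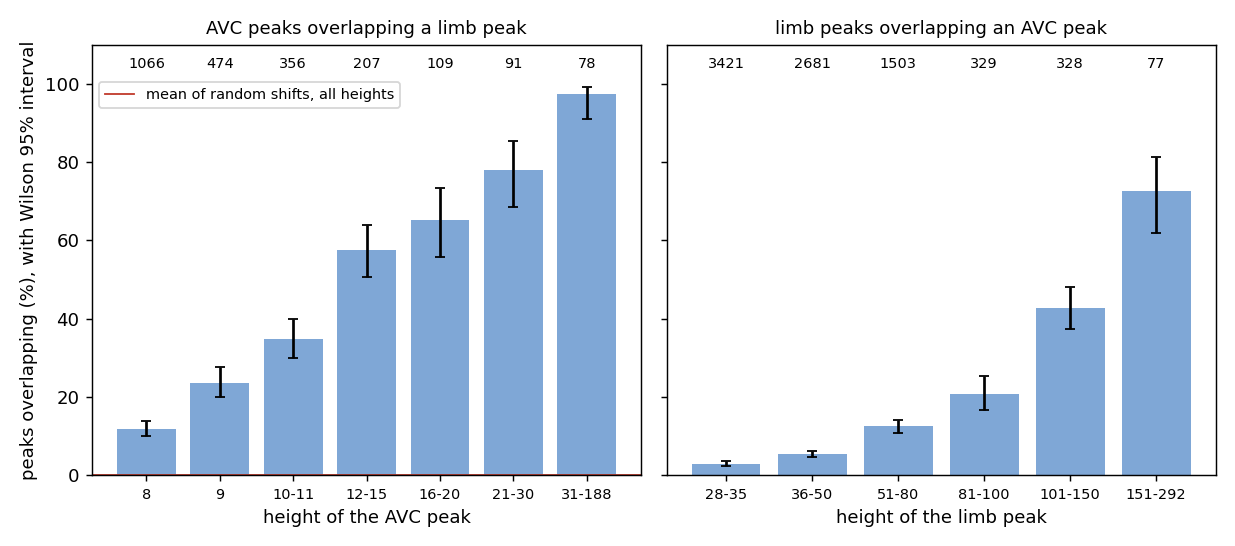
Share of AVC peaks that overlapped a limb peak (left) and of limb peaks that overlapped an AVC peak (right), in percent, by the height of the peak in its own list. Bars are shares with Wilson 95% intervals, numbers above them are peaks, and the red line is the mean of random shifts (0.21%); the shares run from 11.8% to 97.4% in the AVC and from 3.01% to 72.7% in the limb.

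All of the 10 tallest AVC peaks overlapped a limb peak, and all of the 10 tallest limb peaks overlapped an AVC peak. Coordinates are in mm9, the build named in the submitters' processing notes, counted from 1. The tallest peak of both lists was the same site on chromosome 10, at 52106783 to 52107159 in the AVC (height 188) and 52106817 to 52107134 in the limb (height 292). It was followed in the AVC by peaks on chromosome 18 at 34918667 to 34919229 (height 67), on chromosome 10 at 80755847 to 80756162 (height 64) and on chromosome 9 at 107471146 to 107471404 (height 63). The peak on chromosome 18, that on chromosome 10 at 80755847 and an AVC peak on chromosome 5 at 115224534 to 115224917 (height 50) also overlapped limb peaks among the tallest 10, of heights 216, 234 and 234. The AVC peaks that overlapped other tall limb peaks varied in height. The limb peak on chromosome 17 at 8565584 to 8565828 (height 271) overlapped an AVC peak of height 36, among the tallest of its list, and that on chromosome 8 at 89873710 to 89873938 (height 252) an AVC peak of height 9, the median of the AVC list. The tallest AVC peak without a limb peak lay on chromosome 12 at 79451839 to 79452190 and had a height of 37. The tallest limb peak without an AVC peak lay on chromosome 10 at 45613797 to 45614061 and had a height of 213. Both of these were singled out after their values were seen. Not-shared peaks were lower within their lists, with a median height of 8 against 11 for shared ones in the AVC and of 37 against 63 in the limb. An absent limb or AVC peak means that none was in the authors' list, since the depth of each library is unknown. Gene annotation and sequence of the mm9 build were not used here, so peaks are given by position, without the genes around them, and binding was not related to the expression differences.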

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

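The rescaling without erythroid genes and non-coding RNAs, the protein-coding subset, the mesenchyme list without shared members and the limb list with repeated lines were chosen after seeing the data. Counts of genes past the fold rule depended on the settings. Genes at least 2-fold higher in cKO numbered 176 with a pseudocount of 0.1, 41 with a pseudocount of 5, 145 by the authors' deposited fold change and 316 at 1.5-fold, against 82. Genes at least 2-fold lower numbered 335 with a pseudocount of 0.1, 41 with a pseudocount of 5 and 623 at 1.5-fold, against 135. A larger pseudocount shrinks the ratios of low genes by construction. Sox9 kept its direction and stayed past 2-fold in 5 alternatives, with log2 ratios from -1.09 (pseudocount 5) to -1.32 (pseudocount 0.1), both not relative to the median. Of the 88 other named genes, 80 to 86 stayed on their side of the rule in each setting, and none changed direction past it. A pseudocount cannot change the sign of a ratio. Centring, rescaling and the authors' fold change moved most ratios by little. Kept directions of genes past the rule, Sox9 included, were therefore close to fixed in advance. Centring cannot move a list percentile. Rescaling multiplies each genotype by 1 factor, so it can move a percentile only through the pseudocount and the filter. Of 86 list results under the alternatives other than centring, with rescaling included, 82 kept their call. The exceptions were cartilage genes (percentile 4.47) and Wnt genes (2.71) with no filter on low values, neural crest, glial and neuronal markers with a pseudocount of 5 (7.14) and valve mesenchyme markers without shared members (9.38). The cause was not tested. The share of AVC peaks overlapping limb peaks was 27.5% with at least 50% of the AVC peak covered. It was 37.5% (493 of 1315) with each list limited to peaks at or above its median height. With the limb list limited to the AVC list's size, where fewer limb peaks are left to overlap, it was 19.2%. The AVC share over input regions was 10.3% among AVC peaks at or above the median height of their list. No paired analysis was possible because each genotype has 1 merged value, and leaving out single libraries was not possible for the same reason. Peak positions relative to genes, peaks near genes and SOX motifs were not run. The depth of the libraries is unknown, so the precision of low genes and of peaks near the height minimum is unknown too.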

Other observations

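The tests on the all-gene median, on the erythroid genes and on the mesenchyme share were chosen after the result was seen, and the lists of X-linked escape genes, other stress genes and other melanocyte genes were drawn up after the expression table had been read.

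Stress-response genes beyond those in the fixed lists were also higher in cKO. Ddit3, Derl3 and Stc2 (6.21 and 20.7 nFPKM, relative log2 ratio 1.69) stood among the genes past the 2-fold rule, which raised the hypothesis of a wider programme of the unfolded protein and amino acid responses. Of 31 other known members that passed the filter, 29 stood above the all-gene median, and their median of 0.27 was above that of all 10000 matched random lists. Gdf15, a cytokine gene, met the 2-fold rule, near the low end of expression (0.31 and 2.15 nFPKM, 1.37). Ppp1r15a (0.72), Herpud1 (62.3 and 93.5 nFPKM, 0.68), Sdf2l1 (0.66) and Atf4 (147 and 210 nFPKM, 0.62) followed among genes above 10 nFPKM. The test does not separate an effect of the deletion from a difference in the handling of the pools.

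Small nucleolar and Cajal body RNAs spread far more than other transcripts. Of 39 such RNAs, 8 were at least 2-fold higher and 5 at least 2-fold lower after centring, 33.3% against 1.51% of all transcripts. Snora69 stood at 8.62 nFPKM in WT and 112 in cKO, and Snord83b at 13988 and 1654 nFPKM. Non-coding transcripts together made up 14.5% of the summed nFPKM in WT and 11.8% in cKO. These values are given with no explanation.

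Higher markers of several other cell types in cKO, with lower mesenchymal genes, raise the question of whether the cell makeup of the pools differed. A lower share of mesenchyme alone would raise all other cell types alike, but the medians of the erythroid, epicardial, endothelial, cardiomyocyte and macrophage lists spanned 1.24, against 0.30 for the upper end of the middle 95% of matched random lists, and 0.67 against 0.28 without the erythroid list. The random lists hold unrelated genes, while genes of 1 list are often co-expressed, so this range is too narrow a yardstick and the test does not decide. The list medians were not raised alike, at 1.10 for erythroid and 0.53 for epicardial markers against -0.04 for cardiomyocyte and -0.14 for macrophage markers. More blood cells in the cKO pool remain open, since 12 of 12 expressed erythroid genes were above the all-gene median, Alas2 (128 and 253 nFPKM) and Slc4a1 (119 and 200 nFPKM) as well as the globins; none of the 12 is in another list. A larger erythroid share may also account for the all-gene median below 0, which went from -0.11 to -0.0254 when both genotypes were rescaled without the erythroid list, and to -0.0596 when non-coding RNAs were left out too. An effect of the deletion on cell numbers, which Tie2-Cre could have in endothelial and blood lineages, stays open and untested.

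Higher Y-linked genes, which only males carry, together with lower Xist in cKO point to pools of different sex composition. X-linked genes that escape inactivation should then be lower in cKO, and Kdm5c, Eif2s3x, Ddx3x and Kdm6a all were, with a median relative log2 ratio of -0.16. That median lay at percentile 4.55 of random lists, inside their middle 95%. The number above the all-gene median, 0, was at percentile 1.88, outside it. The ranks of the median and of the number differ in their call, and both rest on 4 genes. If Y-linked levels scale with the share of male RNA and Xist with the share of female RNA, the 4 Y-linked genes give a male share of 5.77% to 8.70% in WT and 58.5% to 59.8% in cKO. Sex and genotype are then confounded for any autosomal gene that differs by sex, which was not tested.

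AVC peaks that overlap no limb peak were mostly close to the minimum height, and a candidate explanation is that they are scattered background calls. Of these 1682 peaks, 155 (9.22%) lay within 10 kb of a limb peak, against 6.23% on average and 5.11% to 7.37% in the middle 95% of 1000 random shifts. None of the 1000 shifts gave as many. The shifts also place peaks where no read maps uniquely, which lowers the chance share, so the excess does not decide whether these are background calls. For heights 10 or more the share was 9.74%, and 11 of 1000 shifts were as high. A part or all of the set may still be background, and clustering of calls in open or gene-rich chromatin was not tested.

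The melanocyte genes Dct (8.17 and 1.12 nFPKM) and Pmel (6.42 and 1.85 nFPKM) were at least 2-fold lower in cKO. Of 6 other melanocyte genes that passed the filter, 3 were above and 3 below the all-gene median, with a median of 0.094, against relative log2 ratios of -2.01 for Dct and -1.27 for Pmel. The test, set before this median was seen, took a median above the lower end of the middle 95% of random lists as evidence against fewer melanocytes in the pool. Its members do not allow that reading. Mitf and Kit stood at 37.0 and 18.8 nFPKM in WT, above Dct, so a small melanocyte share could be hidden in them, and Gpnmb, Rab38 and Mlana were under 3 nFPKM in both genotypes. Slc24a5 (6.29 and 5.39 nFPKM) alone was near the level of Dct, and 1 gene does not decide. Fewer melanocytes in the pool and a difference in Dct and Pmel alone cannot be told apart. AVC and input regions had similar shares on the X chromosome, 2.46% (Wilson 95% interval 1.93 to 3.13) and 2.16% (1.93 to 2.41), against 1.18% (0.98 to 1.42) of limb peaks. On the Y chromosome there were 4 AVC peaks, 0 limb peaks and 88 input regions.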
